A study of Homo sapiens with 6 samples.

How the data were processed

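RNA-seq was run on cells labelled MOLM-13, a human acute myeloid leukaemia cell line that carries a KMT2A fusion and an internal tandem duplication of FLT3. Per the labels, cells received 20 nM TSN or the solvent DMSO for 48 h, RNA was extracted with RNAiso Plus, and libraries were sequenced on a NovaSeq X Plus. Whether polyadenylated RNA was selected is not given in the sources used here. The series title names toosendanin, a triterpenoid from the tree Melia toosendan, and TSN is taken here as its abbreviation. There were 3 libraries per group, described as biological replicates in the labels. Groups were taken from the sample titles, because the treatment field of the labels reads DMSO on all 6 samples. In the expression table, 3 columns carry the name TSN and match the TSN titles. The other 3 columns do not carry the word DMSO and were assigned to the DMSO samples because DMSO is the only other group, which is a limit on every comparison.

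The authors deposited a table of 30741 genes with values in FPKM (fragments per kilobase of exon, scaled to library size). The unit is not written in the table and was read from the values. For genes with a single exon, the value multiplied by the exon length fell on whole multiples of 1 step per library, within a tolerance of 0.1, in 97.0% to 97.4% of low values. The size of that step gave an estimate of depth, from 37157320 to 50414831 fragments per library. A single fragment on 1 kb of exon was then worth 0.0198 to 0.0269 FPKM. Over all genes, 72.6% to 76.9% of low values came out whole, so the gene lengths the authors used were not recovered in full and the main test was not run on reconstructed counts. Values times GENCODE exon lengths summed to 143.3% to 150.9% of the estimated fragments. The genome build was GRCh38 and DESeq2 1.26.0 was used, per the submitters' processing notes. The aligner, the counting tool, its use of strand, the gene annotation and the length behind each FPKM are not given in the sources used here. The design text of the series names an adjusted p under 0.05 with an absolute log2 fold change over 0.584 as the authors' criteria.

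FPKM are not counts, so the count test planned for a count table was not used, and the test planned for normalized values was used instead. Values were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and robust moderation. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 11440 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and their errors are standard errors (SE) of the moderated fit. FPKM values are relative to each library's total, so a change in total RNA per cell would not be visible. Group levels are means ± SD over 3 libraries. Gene places, lengths and overlaps came from GENCODE 29 on GRCh38, in which 93.7% of the genes of the table were found by identifier. GC content came from its transcripts.

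Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, where at least 5 genes were tested, and p-values were adjusted over the 31 lists tested. The lists covered cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, MYC targets, nucleotide synthesis, DEAD-box and DEAH-box helicases, splicing factors, and snoRNA hosts with decay factors. They also covered ATF4, NRF2 and p53 targets, endoplasmic reticulum and heat shock chaperones, apoptosis, DNA replication, mitosis, histones, oxidative phosphorylation, glycolysis, cholesterol synthesis and lysosomes. The remaining lists held immature and mature myeloid genes, the KMT2A-fusion program, FLT3 output, interferon, NF-kB and immediate-early genes, and markers of erythroid, megakaryocytic, lymphoid, and epithelial or fibroblast cells. The 13 protein genes of the mitochondrial genome were not analysed here. Named genes followed a rule. MYC and DDX5 were always named. So were the 8 higher and 8 lower genes of largest log2 fold change past the threshold with a mean of at least 5 FPKM in the higher group, no overlap of the groups and an HGNC symbol that is no pseudogene. From each list, the rule took up to 2 higher and 2 lower genes of lowest adjusted p, or, where none passed, up to 2 of highest mean. Groups, tests, lists, this rule and the alternatives, except those named as added later, were fixed before the data were examined.

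The whole procedure was tested on simulated data drawn from the real means, spreads and depths for 11235 genes with known changes between TSN and DMSO. It recovered 74.2% of 4-fold changes, 37.3% of 2-fold changes and 3.0% of 1.5-fold changes, with 6.2% false calls. Only 66 or 67 genes were changed per fold, and noise was drawn independently for each gene and library. The real libraries share variation over many genes, so these rates need not hold for the data. The closest pair of libraries, DMSO 1 and DMSO 2, differed by more than counting error on reconstructed fragments, with a chi-square of 10.2 per degree of freedom over 15220 genes, so they were not merged as 1 library. That check covers counting error only and does not show that libraries are separate cultures. Alternatives covered pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, scaling by median log ratios, quantile normalization, plain moderation, each library left out in turn, a replicate block, an estimated correlation for camera, and fry. Added after the data were seen were removal of each library's trend with exon length and GC content (splines of 5 degrees of freedom, 11242 genes), removal of DMSO 3 and TSN 3 together, voom weights on reconstructed fragments, and library weights. Of the lists and tests chosen after results were seen, 1 gene list and 2 tests on the KMT2A-fusion program are not reported here. The alternatives planned for counts were not run because the table holds FPKM. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.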

Results

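The series compared MOLM-13 leukaemia cells after 48 h in 20 nM TSN with cells in DMSO, in 3 libraries each. The question, from its title, is whether toosendanin acts on this leukaemia by way of DDX5 and MYC and lowers protein synthesis. Estimated depth was 39991349, 41649675 and 37157320 fragments in DMSO 1, 2 and 3, and 50414831, 44284214 and 37760281 fragments in TSN 1, 2 and 3. Between 22170 and 24654 genes had a value above 0 per library. DMSO 1 and DMSO 2 lay close together (r = 0.996 over genes on the log2 scale), while TSN 2 and TSN 3 correlated at r = 0.913. Genes are not independent replicates, so these values only describe the libraries. TSN 3 had the lowest median level of the tested genes, 2.97 on the log2(FPKM + 1) scale against 3.30 to 3.46 in the other libraries.

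**Figure D1:**
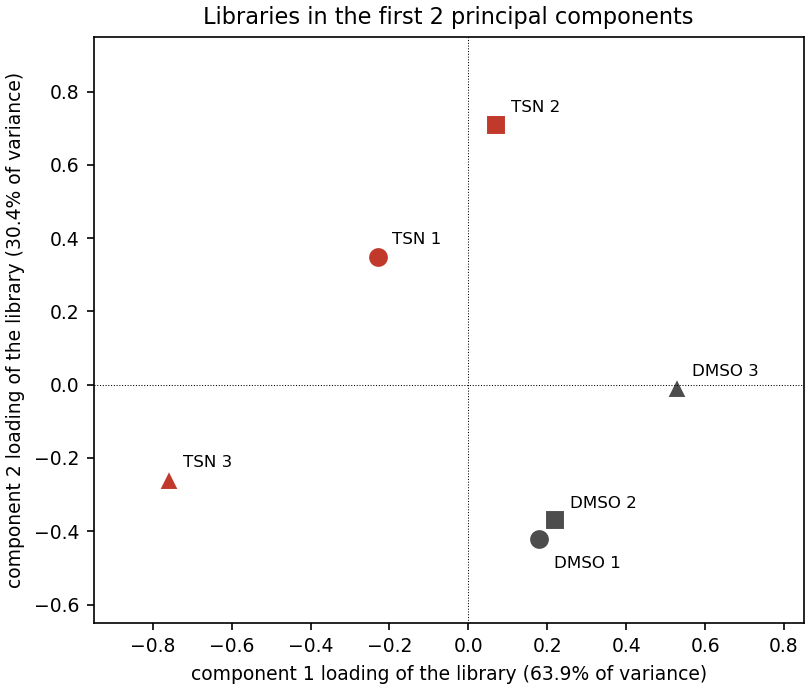
Loadings of the 6 libraries on principal components 1 (x axis, 63.9% of the variance) and 2 (y axis, 30.4%) of log2(FPKM + 1) over the 11440 genes tested, with colour for group and symbol for replicate. DMSO 3 at 0.53 and TSN 3 at -0.76 form the ends of component 1, and DMSO 1 and 2 lie next to each other.

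MYC, a transcription factor that drives growth genes, fell after TSN, whereas no difference in DDX5 passed the test. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) dropped from 211.5 ± 3.13 FPKM in DMSO to 86.57 ± 8.38 in TSN (SD, n = 3), a log2 fold change of -1.28 ± 0.13 SE with a limma adjusted p of 0.00361. All 3 TSN values (92.96, 89.66 and 77.08 FPKM) lay below the 3 DMSO values (215.04, 210.32 and 209.11 FPKM). DDX5, an RNA helicase of the DEAD-box family (ENSG00000108654, chromosome 17, 64499616 to 64508199), stood at 126.4 ± 14.9 FPKM in DMSO and 92.61 ± 31.2 in TSN. Its log2 fold change of -0.50 ± 0.28 SE had a limma adjusted p of 0.274, and the groups overlapped, with 58.46 FPKM in TSN 3 but 119.75 in TSN 2. Without TSN 1, MYC stayed at -1.34 but its limma adjusted p rose to 0.0564. DDX5 was measured here as RNA only, and exons of DDX5 share 6.8% of their bases with CEP95, so that antisense or overlapping fragments cannot be told apart without a stated use of strand.

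**Figure D2:**
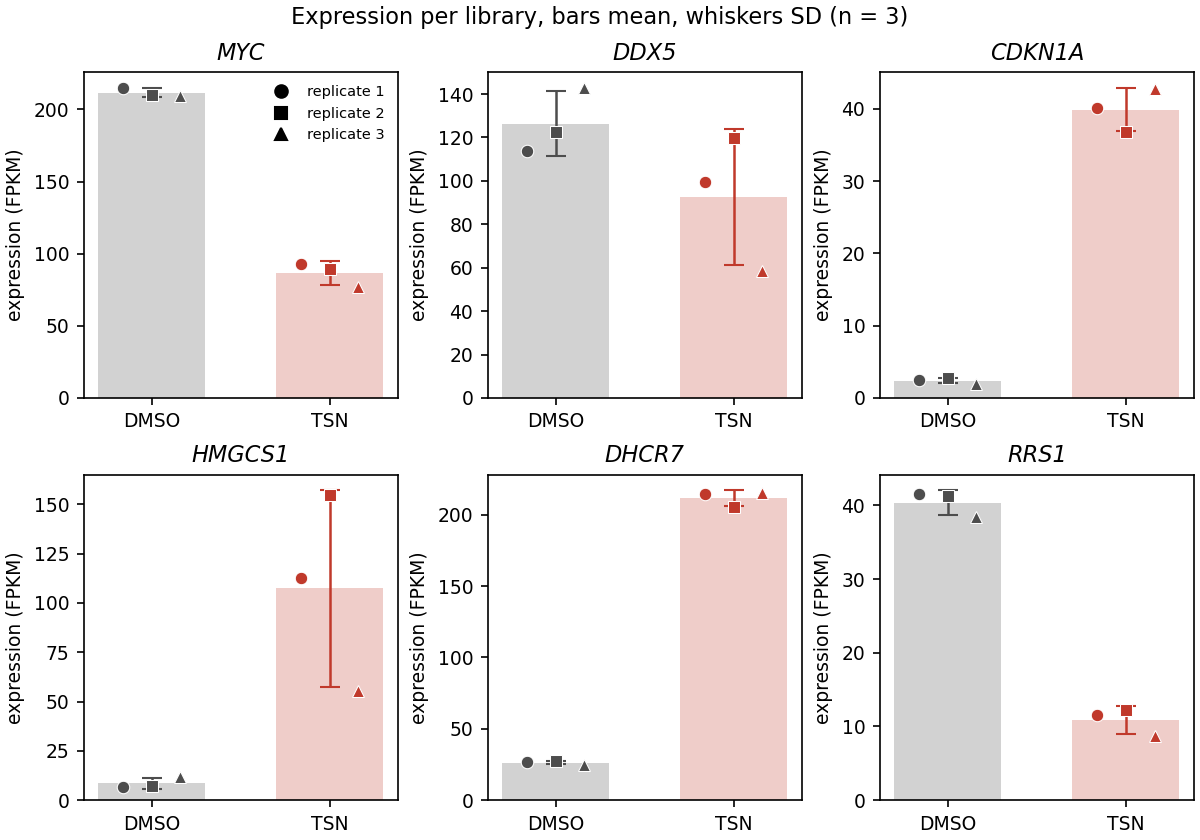
Expression in FPKM (y axes, from 0) of 6 genes in DMSO and TSN libraries, with 1 point per library, bars for group means and whiskers for SD (n = 3 per group). MYC and RRS1 were lower and CDKN1A, HMGCS1 and DHCR7 higher in all 3 TSN libraries, while DDX5 values overlapped between the groups.

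The 8 genes that rose furthest after TSN included ACSS2, the cell cycle inhibitor CDKN1A and the chemokine CXCL8. ACSS2, which makes acetyl-CoA from acetate (chromosome 20, 34872146 to 34927962), rose from 8.738 ± 0.263 to 126.7 ± 4.64 FPKM (log2 fold change 3.71 ± 0.11 SE). CDKN1A (chromosome 6, 36676460 to 36687339) rose from 2.399 ± 0.395 to 39.92 ± 3.02 FPKM (3.59 ± 0.15 SE), and the fatty acid desaturase FADS2 from 17.12 ± 1.26 to 182.7 ± 4.85 FPKM (3.34 ± 0.12 SE). The tubulin gene TUBA1A (3.65 ± 0.16 SE), the sterol synthesis genes HMGCS1 (3.43 ± 0.40 SE) and MVD (3.13 ± 0.34 SE), the aldolase ALDOC (3.08 ± 0.15 SE) and CXCL8 (3.07 ± 0.21 SE) completed the 8 leading genes, with limma adjusted p from 0.000162 to 0.00504. The 8 genes that fell furthest were led by CHAT, the enzyme that makes acetylcholine (chromosome 10, 49609095 to 49665104), from 16.77 ± 3.71 to 2.339 ± 1.31 FPKM (-2.48 ± 0.34 SE). HOXD13, a homeobox transcription factor, fell from 32.98 ± 0.788 to 6.811 ± 1.07 FPKM (-2.13 ± 0.15 SE), and the linker histone gene H1-2 from 14.73 ± 2.58 to 2.919 ± 0.841 FPKM (-2.01 ± 0.22 SE). SOX18 (-1.89), ZNHIT2 (-1.84), G0S2 (-1.82), the ribosome assembly factor RRS1 (-1.82) and the long noncoding RNA BALR6 (-1.81) followed, and limma adjusted p for these 8 ran from 0.00129 to 0.0362.

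Over all 11440 genes, 882 rose and 824 fell at a limma adjusted p under 0.05, 1706 in all, of which 794 and 730 also passed the log2 fold change of 0.584 of the series text. The 3 values of each group did not overlap in 4479 genes (39.2%, against 10% by chance). The count varied with the libraries kept and with the filter, with 312 genes without DMSO 1, 247 without DMSO 2, 437 without DMSO 3, 24 without TSN 1 (where 7 of the 16 leading genes kept their call), 1779 without TSN 2 and 2513 without TSN 3. A fit with 1 library left out also has fewer residual degrees of freedom, so a lost call need not mean a changed effect. These 2 sources of change in the count were not separated. In the same fits, the log2 fold change of MYC ran from -1.34 to -1.20, and 17 to 19 lists passed by camera. It was 777 with no filter, 1002 with a mean of at least 5 FPKM and 2978 without both DMSO 3 and TSN 3, a choice made after the data were seen. The number of called genes per list varied in the same way: without TSN 1, 7 of the 31 lists had any call, against 29 in the main fit. Scaling by median log ratios moved the median log2 fold change of all genes by 0.11, from -0.10 to 0.01, and the share of higher calls from 51.7% to 60.3% (1170 higher and 771 lower).

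Genes of cholesterol synthesis and uptake rose almost throughout. Of 22 tested, 19 rose and 0 fell (20 rose when adjusted over the list alone; 5 to 21 with 1 library left out), with a median log2 fold change of 2.13. DHCR7, the last enzyme of one branch of the pathway, rose from 26.39 ± 1.31 to 211.7 ± 5.62 FPKM (2.96 ± 0.12 SE, limma adjusted p = 0.000283). ACAT2, which condenses acetyl-CoA at its start, rose from 35.57 ± 1.92 to 231.1 ± 25.3 FPKM (2.66 ± 0.14 SE, limma adjusted p = 0.000514). The list was higher by camera (adjusted p = 3.9e-19) and stayed so with an estimated correlation between genes (adjusted p = 0.046), the 1 list of 31 that did. Exons of ACAT2 share 33.9% of their bases with SOD2-OT1 and exons of HMGCS1 also overlap another gene, so both values are less certain.

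**Figure D3:**
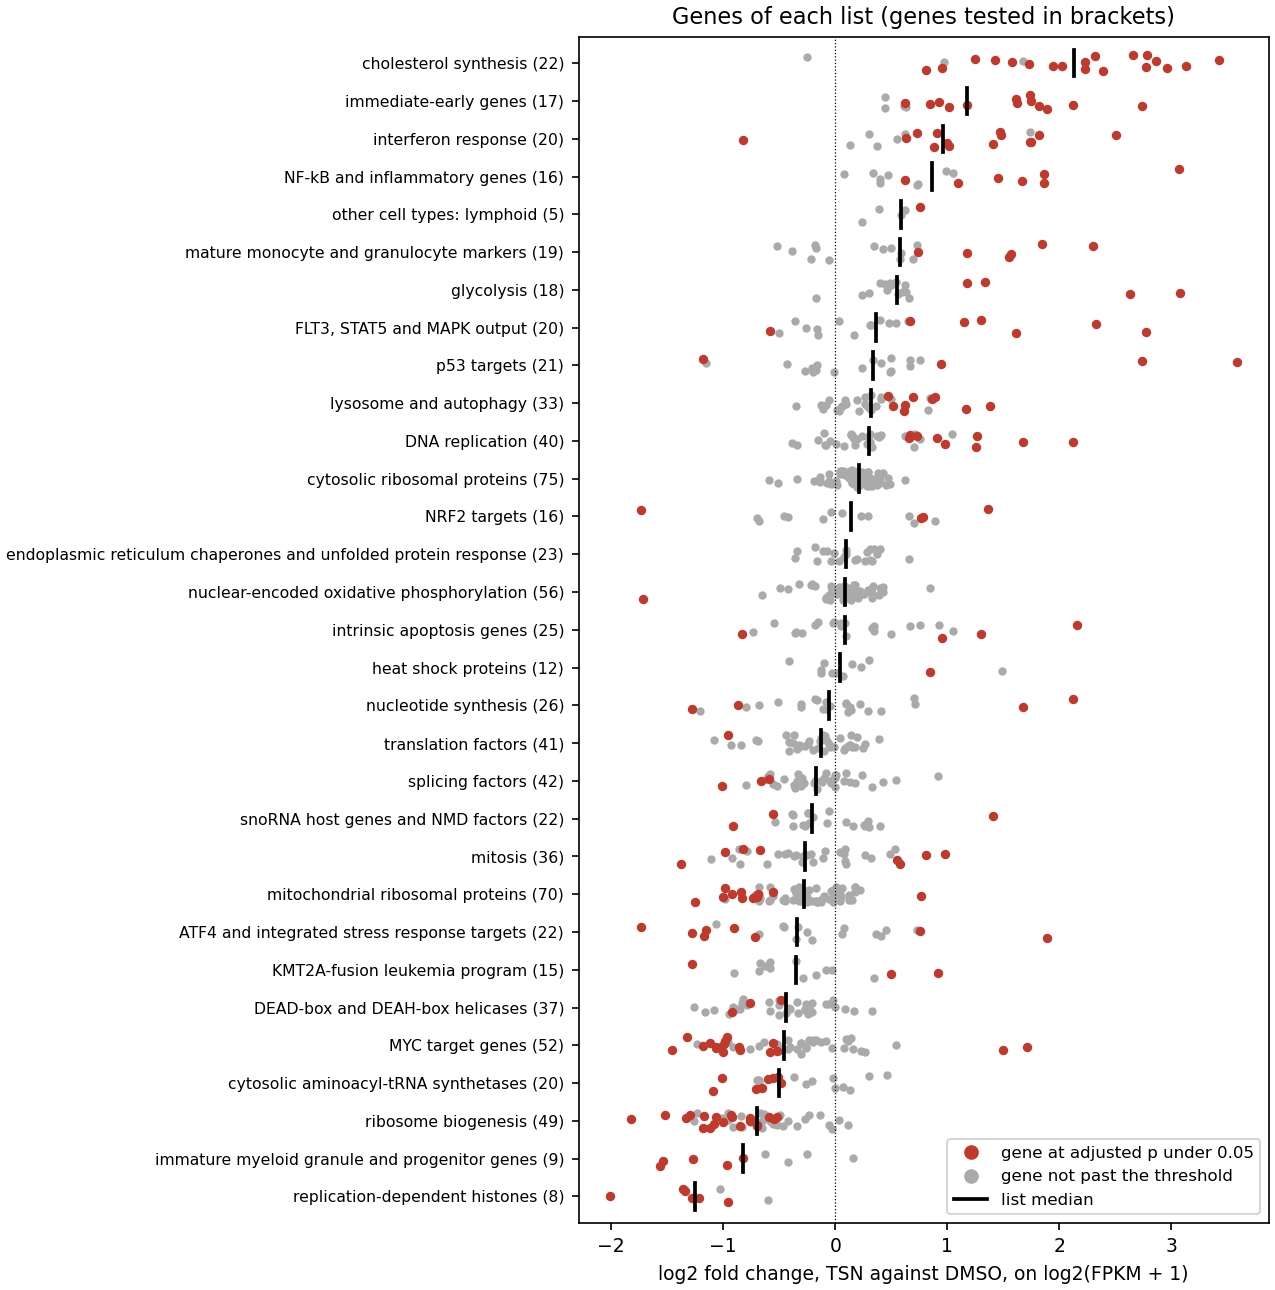
Log2 fold changes between TSN and DMSO on the log2(FPKM + 1) scale (x axis) of the tested genes of 31 lists (y axis, genes tested in brackets), red where the limma adjusted p was under 0.05, with a black line at each list's median. Medians run from 2.13 for cholesterol synthesis to -1.25 for replication-dependent histones.

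Many genes that build ribosomes fell, as did part of the MYC targets and of the aminoacyl-tRNA synthetases, which charge tRNA. In ribosome biogenesis, 20 of 49 genes fell and 0 rose (33 fell when adjusted over the list alone; 0 to 28 with 1 library left out), with a median of -0.70. RRS1 fell from 40.37 ± 1.7 to 10.83 ± 1.91 FPKM (limma adjusted p = 0.00253) and BYSL, a factor of the small subunit, from 81.96 ± 6.55 to 37.0 ± 2.26 FPKM (-1.12 ± 0.13 SE, limma adjusted p = 0.00438). The list was lower by camera (adjusted p = 2.2e-11), with an adjusted p = 0.068 with an estimated correlation. Among 52 MYC targets, 16 fell and 2 rose (22 and 3 when adjusted over the list alone; 0 to 23 fell with 1 library left out), and 14 of the 52 also stand in the ribosome biogenesis list. ODC1, which starts polyamine synthesis, fell from 199.9 ± 10.3 to 97.99 ± 2.29 FPKM (-1.02 ± 0.12 SE), while TMEM97, a sterol-regulated protein (1.5 ± 0.13 SE), and the transferrin receptor TFRC (1.71 ± 0.35 SE) rose. For MYC targets the camera adjusted p was 0.00011, with an adjusted p = 0.098 with an estimated correlation. Of 20 genes in the list of cytosolic aminoacyl-tRNA synthetases, which includes the complex proteins AIMP1, AIMP2 and EEF1E1, 8 fell and 0 rose (8 when adjusted over the list alone; 0 to 10 with 1 library left out, 0 without DMSO 1, DMSO 2, DMSO 3 or TSN 1). These were 6 synthetases with AIMP1 and AIMP2, among them MARS1 from 213.6 ± 8.79 to 103.0 ± 28.9 FPKM (-1.09 ± 0.23 SE) and FARSB (-0.71 ± 0.13 SE). Their camera adjusted p was 0.0079, with an adjusted p = 0.44 with an estimated correlation.

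Of 70 mitochondrial ribosomal protein genes, 10 fell and 1 rose (11 and 1 when adjusted over the list alone; 0 to 22 fell with 1 library left out). MRPL58 fell from 58.93 ± 5.95 to 24.24 ± 2.8 FPKM (-1.25 ± 0.15 SE), MRPL46 fell by 0.83 and MRPS6 rose by 0.77 on the log2 scale. By camera the list had an adjusted p of 0.0014, with an adjusted p = 0.61 with an estimated correlation, and without TSN 2 the median was -0.17 with a camera adjusted p of 0.28. Among 37 DEAD-box helicases, the family of DDX5, and DEAH-box helicases, 3 fell and 0 rose (2 fell when adjusted over the list alone; 0 to 10 with 1 library left out). These were the DEAD-box gene DDX10 (-0.92 ± 0.16 SE) and the DEAH-box genes DHX37 (-0.76 ± 0.12 SE) and DHX30 (-0.48). Over all 11440 genes tested, 824 fell. The camera adjusted p of this list was 0.00058, with an adjusted p = 0.48 with an estimated correlation. Cytosolic ribosomal protein genes had 0 calls by limma among 75 in either direction (also 0 when adjusted over the list alone, and 1 at an unadjusted p under 0.05). RPS6 stood at 3570 ± 519 and 4574 ± 1270 FPKM (limma adjusted p = 0.432) and RPLP0 at 2133 ± 367 and 2565 ± 1010 FPKM (limma adjusted p = 0.693). Their median of 0.21 was higher by camera (adjusted p = 0.036), with an adjusted p = 0.78 with an estimated correlation. That direction went with TSN 3, in which RPS6 reached 5957.92 FPKM, since the median was -0.12 without TSN 3 (camera adjusted p = 0.23), 0.01 without DMSO 3 and 0.02 after quantile normalization, where camera pointed the other way. Without both DMSO 3 and TSN 3, a choice made after the data were seen, the list passed as lower (median -0.28, camera adjusted p = 3e-04). Of 41 translation factors, EIF3J fell (-0.96 ± 0.19 SE, 0 calls when adjusted over the list alone) and 0 rose, and the list did not pass (camera adjusted p = 0.25; lower with no filter, camera adjusted p = 0.036). Some genes of the last 2 lists had low values, such as EIF5A (4.17 FPKM in DMSO) beside EEF1A1 (4560), and RPL7A (1.6). Such values may understate a level, so the lack of a call need not mean no change in those genes.

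Some DNA replication genes and the cell cycle inhibitor CDKN1A rose in the same libraries in which most of the histone genes tested fell. Of 40 DNA replication genes, 9 rose and 0 fell (9 when adjusted over the list alone; 0 to 14 with 1 library left out). RRM2, a subunit of ribonucleotide reductase, rose from 40.95 ± 2.59 to 135.2 ± 27.8 FPKM (1.68 ± 0.18 SE) and the replication licensing factor CDC6 from 18.36 ± 0.749 to 45.6 ± 6.37 FPKM (1.26 ± 0.15 SE). By camera, replication genes were higher as a list (adjusted p = 2.6e-06), with an adjusted p = 0.11 with an estimated correlation. Of 8 replication-dependent histone genes that reached the filter, from a list of 15, 6 fell and 0 rose (8 fell when adjusted over the list alone; 0 to 7 with 1 library left out), with a median of -1.25. Whether polyadenylated RNA was selected is not known, so these values need not stand for all histone transcripts. H2BC12 fell from 33.65 ± 2.39 to 12.74 ± 1.7 FPKM (-1.34 ± 0.15 SE) and H2AC6 from 4.248 ± 0.6 to 1.037 ± 0.189 FPKM (-1.36 ± 0.15 SE), although near-identical histone genes can share reads. The histone list had a camera adjusted p of 3e-06, with an adjusted p = 0.098 with an estimated correlation. Mitosis genes moved both ways, with 4 higher and 4 lower of 36 (5 and 6 when adjusted over the list alone; camera adjusted p = 0.37). CDK1 (0.58 ± 0.12 SE) and the kinesin KIF2C (0.55 ± 0.11 SE) rose, while the kinase PLK1 (-0.98 ± 0.12 SE) and CDC20 (-0.82 ± 0.15 SE) fell. Nucleotide synthesis also split, with TK1 (2.12 ± 0.31 SE) and RRM2 higher and DHODH (-1.28 ± 0.13 SE) and UMPS (-0.87 ± 0.13 SE), enzymes of pyrimidine synthesis, lower among 26 genes (2 higher and 4 lower when adjusted over the list alone). That list did not pass (camera adjusted p = 0.85), and its median of -0.06 and mean of 0.00 stood against a camera direction of higher. Of 21 p53 targets, 3 rose and 1 fell (5 and 1 when adjusted over the list alone; 1 to 5 rose with 1 library left out): BTG2, an antiproliferative gene, rose from 0.7414 ± 0.215 to 10.6 ± 0.966 FPKM beside CDKN1A, and TRIAP1 fell (-1.18 ± 0.19 SE). The camera adjusted p was 0.026, with an adjusted p = 0.34 with an estimated correlation, and a camera adjusted p of 0.097 without TSN 2. Exons of RRM2 share 20.2% of their bases with another gene.

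Most immediate-early genes and part of the inflammatory and interferon-response genes rose. Of 17 immediate-early genes, 13 rose and 0 fell (15 when adjusted over the list alone; 1 to 11 with 1 library left out), with a median of 1.18. Those of lowest adjusted p were BTG2 (2.74 ± 0.16 SE) and the nuclear receptor NR4A1 (1.75 ± 0.14 SE, from 1.68 ± 0.062 to 8.07 ± 0.86 FPKM). The list was higher by camera, adjusted p = 4e-12, with an adjusted p = 0.068 with an estimated correlation. Of 16 NF-kB and inflammatory genes, 7 rose and 0 fell (10 when adjusted over the list alone; 1 to 10 with 1 library left out): CXCL8 rose from 8.408 ± 1.55 to 78.46 ± 15.5 FPKM and NFKB2, a subunit of the factor itself, from 46.52 ± 4.44 to 150.3 ± 8.78 FPKM (1.67 ± 0.13 SE). Their camera adjusted p was 7.9e-09, with an adjusted p = 0.068 with an estimated correlation. In the interferon response, 13 of 20 rose and 1 fell (15 and 1 when adjusted over the list alone; 0 to 12 rose with 1 library left out). The number that rose was 0 without TSN 1, 2 without DMSO 1, 2 without DMSO 2 and 3 without DMSO 3. IFI6 rose from 3.711 ± 1.17 to 26.46 ± 10.3 FPKM (2.51 ± 0.32 SE) and OASL from 0.2131 ± 0.0834 to 3.064 ± 0.452 FPKM, while MX2 fell from 29.51 ± 3.39 to 16.41 ± 3.27 FPKM (-0.82 ± 0.18 SE). The camera adjusted p was 3.9e-09, with an adjusted p = 0.093 with an estimated correlation. Genes read as output of FLT3, STAT5 and MAPK signalling rose in 6 and fell in 1 of 20 (7 and 2 when adjusted over the list alone; 2 to 8 rose with 1 library left out). The kinase PIM1 (2.33 ± 0.15 SE) and the phosphatase DUSP5 (2.77 ± 0.18 SE) rose and SOCS2 fell (-0.58 ± 0.13 SE), with a camera adjusted p of 0.00066 and an adjusted p = 0.31 with an estimated correlation.

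Some markers of mature monocytes and granulocytes rose, and part of the genes of immature myeloid cells fell. Of 19 mature markers, 6 rose and 0 fell (10 and 1 when adjusted over the list alone; 1 to 10 rose with 1 library left out). The transcription factor IRF8 rose from 2.621 ± 0.162 to 12.07 ± 0.465 FPKM (1.85 ± 0.13 SE) and the oxidase subunit NCF1, which has near-identical pseudogenes, from 2.24 ± 0.164 to 15.73 ± 6.47 FPKM (2.30 ± 0.28 SE). The camera adjusted p was 9.1e-05, with an adjusted p = 0.098 with an estimated correlation. Of 9 immature genes, 5 fell and 0 rose (6 when adjusted over the list alone; 0 to 7 with 1 library left out). Among these were the granule protease CTSG, from 19.1 ± 1.85 to 5.993 ± 2.06 FPKM (-1.56 ± 0.23 SE), and MS4A3 (-1.54 ± 0.24 SE). Their camera adjusted p was 0.0018, with an adjusted p = 0.098 with an estimated correlation. In the KMT2A-fusion program, PBX3 (0.92 ± 0.19 SE) and LMO2 (0.50 ± 0.13 SE) rose and MYC fell among 15 genes tested (3 and 4 when adjusted over the list alone; camera adjusted p = 0.30). Only 15 of its 22 genes reached the filter, and 7 were listed below 1 FPKM in all 6 libraries. Of 5 lymphoid genes tested, CD3D rose from 0.972 ± 0.085 to 2.359 ± 0.566 FPKM and 0 fell (2 when adjusted over the list alone), where the camera adjusted p was 0.018, with an adjusted p = 0.44 with an estimated correlation, and a camera adjusted p of 0.056 after median log ratio scaling. Too few genes passed the filter to test 3 further lists. GATA1 (25.99 ± 11.7 FPKM in TSN, 13.84 ± 3.27 in DMSO, limma adjusted p = 0.173) and EPOR (log2 fold change -0.40, limma adjusted p = 0.164) stood for 2 erythroid genes tested, the megakaryocytic ITGA2B rose (0.68 ± 0.13 SE), and KRT18 rose by 1.69 ± 0.28 SE among 3 epithelial or fibroblast genes.

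Glycolysis and lysosome genes rose in part, and stress-response lists mostly did not pass. Of 18 glycolysis genes, 4 rose and 0 fell (10 when adjusted over the list alone; 1 to 10 with 1 library left out). They included ALDOC, from 7.839 ± 0.586 to 73.9 ± 10.5 FPKM, and the enolase ENO2, from 0.5646 ± 0.143 to 8.666 ± 1.06 FPKM (2.63 ± 0.15 SE). Glycolysis was higher by camera (adjusted p = 1.9e-07), with an adjusted p = 0.068 with an estimated correlation. Of 33 lysosome and autophagy genes, 9 rose and 0 fell (9 when adjusted over the list alone; 0 to 13 with 1 library left out, 0 without DMSO 1, DMSO 2, DMSO 3 or TSN 1). Among them were the proton pump subunits ATP6V1H (0.89 ± 0.14 SE) and ATP6V1E1 (1.17 ± 0.21 SE). The camera adjusted p was 1.4e-05, with an adjusted p = 0.093 with an estimated correlation. Among 22 ATF4 targets, 2 rose and 6 fell (2 and 7 when adjusted over the list alone; camera adjusted p = 0.15). The transcription factor ATF3 rose from 5.646 ± 0.49 to 23.75 ± 3.09 FPKM (1.89 ± 0.16 SE) and DDIT4 rose (0.76 ± 0.15 SE), while the serine synthesis enzyme PSAT1 (-1.28 ± 0.16 SE) and the cystine transporter SLC7A11 (-1.73 ± 0.23 SE) fell. NRF2 targets gave ME1 (1.36 ± 0.18 SE) and PGD (0.78 ± 0.13 SE) higher and SLC7A11 lower, 3 and 1 of 16 in all (5 and 1 when adjusted over the list alone; camera adjusted p = 0.21). Apoptosis genes gave 3 higher and 1 lower of 25 (4 and 1 when adjusted over the list alone; camera adjusted p = 0.076), with BIK (2.16 ± 0.26 SE) and BCL2A1 (1.30 ± 0.19 SE) higher and CASP6 lower (-0.83 ± 0.18 SE).

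The heat shock list had 1 call of 12, HSPA8, from 419.9 ± 16.3 to 756.4 ± 54.3 FPKM (0.85 ± 0.15 SE; also 1 when adjusted over the list alone; camera adjusted p = 0.30). Chaperones of the endoplasmic reticulum had 0 calls among 23 by limma (also 0 when adjusted over the list alone, and 2 at an unadjusted p under 0.05; camera adjusted p = 0.13). CALR stood at 1688 ± 65 FPKM in DMSO and 1334 ± 95.1 in TSN (limma adjusted p = 0.204) and HSP90B1 at 177.6 ± 4.82 and 169.5 ± 17 FPKM (limma adjusted p = 0.758). Without TSN 3, 3 of them rose and the list passed as higher (median 0.15, camera adjusted p = 0.017). Nuclear-encoded oxidative phosphorylation had 1 call of 56, SDHB, from 27.69 ± 1.96 to 8.087 ± 3.21 FPKM (-1.72 ± 0.27 SE; also 1 when adjusted over the list alone; camera adjusted p = 0.26). The list's median of 0.09 was -0.18 without TSN 3 (camera adjusted p = 0.13), but the list passed as higher without TSN 2 (0.36, camera adjusted p = 0.00018). It passed as lower without both DMSO 3 and TSN 3 (-0.31, camera adjusted p = 0.00073), a choice made after the data were seen. Of 42 splicing factors, 3 fell and 0 rose (0 when adjusted over the list alone; camera adjusted p = 0.11, but 0.0066 with no filter and 0.043 with quantile normalization), with SRSF6 (-0.66 ± 0.12 SE) and SRSF2 (-0.59 ± 0.13 SE) among them. Of 22 snoRNA hosts and decay factors, SNHG12 rose (1.41 ± 0.15 SE) and SNHG15 (-0.91 ± 0.17 SE) and UPF3A (-0.56 ± 0.14 SE) fell (also 1 and 2 when adjusted over the list alone; camera adjusted p = 0.67). Exons of SRSF2 share 36.7% of their bases with MFSD11 and those of DDIT4 41.2% with DDIT4-AS1, and the counting is not stated to use strand.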

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

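Removal of the length and GC trend, removal of DMSO 3 with TSN 3, voom weights and library weights were tests chosen only after the result was seen, and the rest were planned. By limma, 777 genes changed with no filter, 1002 with a mean of at least 5 FPKM, 24 to 2513 with 1 library left out, 2949 with the exon length and GC trend removed, 2978 without DMSO 3 and TSN 3, and 8161 with library weights, an estimate that stopped before convergence and gave TSN 1 nearly all the weight. The filters changed how many genes were tested (30741 and 7435), and the cause of the other moves was not tested. Both pseudocounts, both scalings, plain moderation, voom weights and the fold threshold gave 1524 to 2252 genes. With a replicate block, limma called 0 genes and 2121 had an unadjusted p under 0.05, MYC stayed at -1.28 (adjusted p = 0.105), and 19 lists passed. Libraries of the same number did not deviate together (r = -0.32, -0.65 and -0.83), and no library deviated most like its own number in the other group. That gives no sign of pairing by number but cannot exclude it, since part of the differences within groups followed exon length and GC content.

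MYC ranged from -1.34 to -1.20 with 1 library left out (adjusted p = 0.0026 to 0.0564), and DDX5 from -0.71 to -0.20 (adjusted p = 0.0917 to 0.542). MYC lost its call without TSN 1 and under the replicate block and kept it elsewhere. DDX5 passed only with library weights (-0.27, adjusted p = 0.00369). Of 31 lists, 19 passed, 17 to 19 with 1 library left out, 17 by directional fry, 26 by mixed fry and 1 with an estimated correlation, which adds each list's own correlation and leaves only the residual degrees of freedom of 6 libraries. Over 85 named genes, 1208 comparisons kept direction and side of the threshold, 285 lost it (the block included), 7 gained it and 8 reversed. HSP90B1 reversed with median log ratio scaling (0.06), without TSN 3 (0.01), with the length and GC trend removed (0.04), without DMSO 3 and TSN 3 (0.02) and with library weights (0.01). RPLP0 ranged from -0.09 without TSN 3 to 0.46 without TSN 2 and was at -0.24 without DMSO 3 and TSN 3, where RPS6, up to 0.51 without TSN 2, was at 0.00. Cytosolic ribosomal proteins reversed with quantile normalization (median 0.02), without TSN 3 (-0.12, against 0.51 without TSN 2) and without DMSO 3 and TSN 3, where they passed as lower (-0.28, camera adjusted p = 3e-04). Oxidative phosphorylation reversed without DMSO 3 (-0.03), without TSN 3 (-0.18), without both, where it passed as lower (-0.31, camera adjusted p = 0.00073), and with library weights (-0.09), and it passed as higher without TSN 2 (0.36, camera adjusted p = 0.00018). Nucleotide synthesis reversed with no filter and by directional fry (both -0.06), snoRNA hosts by test without TSN 2 (-0.15, with a range of medians up to -0.05) and mitosis without DMSO 3 and TSN 3 (0.03, against -0.46 without TSN 2), while without TSN 3 alone its median was also 0.03 (camera adjusted p = 0.91). Calls were gained by chaperones of the endoplasmic reticulum without TSN 3 (adjusted p = 0.017), without DMSO 3 and TSN 3 (0.043) and with library weights (0.018), by translation factors with no filter (0.036), and by splicing factors with no filter (0.0066) and quantile normalization (0.043). ATF4 targets gained one with quantile normalization (0.047), and apoptosis with it (0.048), a mean of at least 5 FPKM (0.032), the trend removed (0.042) and library weights (0.043). By directional fry, ATF4 targets (fry adjusted p = 0.0061) and NRF2 targets (0.041) gained a call. Cytosolic (0.74) and mitochondrial ribosomal proteins (0.085), helicases (0.07) and lymphoid genes (0.083) lost theirs by directional fry. The cause was not tested. Alternatives planned for counts (TMM, size factors, upper quartile, DESeq2, edgeR and filters on counts) were not run because the values are FPKM. In simulated data, whose noise was independent between genes, 3.0% of 1.5-fold changes were recovered, so small changes were mostly not detectable there with 3 libraries per group.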

Other observations

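The gene lists of this part, the tests on the KMT2A-fusion program and the removal of the length and GC trend were chosen only after results were seen. Of 11 genes of fatty acid synthesis and desaturation tested, 4 rose and 0 fell by limma. FADS1 rose from 6.85 ± 1.31 to 51.4 ± 17.7 FPKM (log2 fold change 2.69 ± 0.28 SE, limma adjusted p = 0.00412) and the stearoyl-CoA desaturase SCD from 69.4 ± 10.3 to 197 ± 66.7 FPKM (1.44 ± 0.27 SE, limma adjusted p = 0.0207), beside FADS2 and ACSS2. FASN (0.65 ± 0.18 SE, limma adjusted p = 0.0575) and SREBF1 (-0.08 ± 0.12 SE, limma adjusted p = 0.70) did not pass.

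Some tubulin genes also rose. Among 8 tested, 3 rose and 0 fell by limma: TUBA1A, TUBA1C (0.64 ± 0.15 SE) and TUBB2A (0.78 ± 0.13 SE). TUBB4B stood at 443 ± 54.1 FPKM in DMSO and 248 ± 64.9 in TSN (limma adjusted p = 0.0519). Reads can be shared between TUBA1A and TUBA1C, whose exons overlap in 14.3% of bases.

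Principal component 1 over all 6 libraries holds 63.9% of the variance, with DMSO 3 and TSN 3 at its ends. Treatment was left in. The loadings were 0.18, 0.22 and 0.53 in DMSO 1, 2 and 3, and -0.23, 0.07 and -0.76 in TSN 1, 2 and 3. They differed both between the groups and within them, so the 63.9% is not spread within a treatment alone. Depth is argued against only as what separates DMSO 3 from TSN 3, which had 37157320 and 37760281 estimated fragments. Over 6 libraries, component 1 followed depth with a Spearman correlation of -0.37 (exact permutation p = 0.50) and a Pearson r of -0.14 (exact permutation p = 0.78), 1 relation computed. Without the 2 farthest in depth, r was 0.68. These correlations cannot decide on depth, because 6 libraries are few and the component also carries the difference between the groups. Exon length and GC content are a candidate explanation: a spline in both took up 0.34 of the variance over genes of TSN 3 against TSN 2 and 0.35 of DMSO 3 against DMSO 1. It also took up 0.27 of TSN 1 against TSN 2, a pair without either end library, but 0.04 of DMSO 1 against DMSO 2. No biological explanation was tested. In TSN 3 against TSN 2, the median log2 difference was 0.30 in genes with under 2.65 kb of exon and -0.73 in genes with over 7.03 kb.

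Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 1706 genes by limma, and the highest of the others gave 0. Such splits are too few for a share under 0.05. All the other splits also put TSN and DMSO libraries in the same group. A treatment effect then adds to the spread within groups and lowers the number of calls, so 0 calls there is no measure of what chance would give. At an unadjusted p under 0.05 the others gave 15 to 1685 genes, the last with TSN 3 beside DMSO 1 and 2.

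The rise of cholesterol synthesis genes may be a response to low cell sterol, which is a hypothesis. Length and GC bias is argued against as its whole cause, since 19 of the 19 called genes stayed called by limma with that trend removed, which left a median of 2.14. If low sterol were read by both SREBP2, which drives sterol synthesis, and LXR, which drives sterol export, LXR targets would fall. Their median was -0.26 over 6 genes that went both ways, with ABCA1 lower (-1.31 ± 0.31 SE, limma adjusted p = 0.0359) and APOE higher (1.45 ± 0.19 SE, limma adjusted p = 0.00709), so that this reading and others cannot be told apart.

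Several genes that KMT2A fusions are known to drive were listed near the floor in all 6 libraries, with MEIS1 at a mean of 0.254 FPKM, HOXA7 at 0.0575 and HOXA9 at 0.872, chosen after their values were seen. HOXA9 reached 1.13 FPKM and is not among the 7 genes below 1 FPKM in all libraries. Loss of fragments where genes overlap stays open for the 7 genes below 1 FPKM. In the GENCODE exons used here their median overlap was 4.0% of exon bases, with 62.5% in HOXA7 and 39.3% in HOXA6. The authors' gene annotation, counting tool and use of strand are not given, so a low overlap in GENCODE cannot exclude such loss in their counting. RPS18 (mean 0.713 FPKM) and RPS25 (0.0258), ribosomal protein genes which every cell uses, were also listed below 1 FPKM in all 6 libraries, chosen after their values were seen, so a value near the floor need not be a low level. Such values were rarer among cytosolic ribosomal protein genes, of which 75 of 79 reached the filter, against 15 of 22 in the KMT2A-fusion program. Reaching the filter does not show that a gene was counted in full. RPL7A (1.6 FPKM in DMSO) and RPS9 (4.72) reached it far below RPS6 (3570), and were chosen after their values were seen. The contrast between the lists therefore does not show that the program genes were low in the cells. Cells of another origin than the label names cannot be told apart from values that understate a level, because no reference profile of the line was used here. In the same list, 6 genes had a mean of at least 10 FPKM (MYC, MYB, LMO2, HOXA10, RUNX2 and JMJD1C). Whether such levels are particular to cells with a KMT2A fusion was not tested, so they do not decide the origin of the cells. No biological explanation was tested, and these 7 genes were listed below 1 FPKM in DMSO and TSN libraries.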
